A study of Homo sapiens with 18 samples.

How the data were processed

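Total RNA of peripheral blood mononuclear cells (the lymphocytes and monocytes left after density gradient separation of whole blood) had been hybridised to Affymetrix Human Genome expression arrays, 1 array per donor. The labels give 10 arrays of donors with untreated chronic hepatitis C virus (HCV) infection of genotype 1 and 8 arrays of healthy donors. In the titles of 2 healthy arrays, numbered 7 and 8, the submitters wrote that the array is an outlier. These 2 arrays were kept as a group of their own and were left out of the main comparison, which set 10 HCV arrays against 6 healthy arrays.

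The deposited table holds log2 expression values of 22283 probe sets on 18 arrays. They were made with GCRMA, a method of background correction, normalization and summary of probe intensities, per the submitters' processing notes. The version of GCRMA and its settings are not given in the sources used here, and the probe intensities were not used here. The array medians lay close to log2 4, about 50% of the probe sets were above log2 4 on each array, and 35.6% to 38.0% of the values of an array lay below log2 2.2, near the floor of the scale. Fold changes of genes near that floor depend on the background correction. Values also repeat exactly between arrays of a run, at high levels too, and the repeated values differ between genes and between runs, so no fold is given for the genes at the extremes with such repeats in the lower group. For arrays, their number limits the precision.

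Gene names came from the platform annotation. Of the probe sets, 19071 carried 1 gene symbol, 1043 carried several and 2169 carried none. Of the 68 control probe sets, 62 carried none and 6 carried 1. Symbols were looked up in the RefSeq gene table of assembly GRCh38.p14, which was used for names only. It matched 19059 probe sets and changed 0 symbols. Probe sets with several symbols or none were left out, as were the 6 control probe sets with 1 symbol and 33 probe sets of sex-linked genes. The 19032 probe sets that remained stand for 11938 genes. Each gene was represented by the probe set with the highest mean over the 16 arrays, and it was tested if its log2 value was above 4 on at least 6 arrays, which left 6688 genes.

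Differences per gene were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A positive log2 fold change means a higher value in HCV. Gene lists, 33 in all with 721 entries, were fixed before the data were examined, and so were the tests, the filter and the alternatives, except where stated otherwise. Of the entries, 613 had a named probe set, and 31 lists had at least 5 tested genes. Lists were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01, and again with an estimated correlation. A score per array, the mean log2 value of a list's tested genes, was compared between groups with an exact two-sided permutation test over all 8008 splits of the 16 arrays, adjusted over the 31 lists. Lists overlap, and adjusted counts "over the list alone" apply the adjustment to a list's own members.

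The genes named in the text were chosen by a rule: the 12 highest and the 12 lowest fold changes past the threshold, without symbols of uncharacterised genes. For each list the rule added up to 2 members that rose and 2 that fell, or the member with the smallest p where none passed. IFI27, ISG15, USP18, CXCL10, IFI44L and MX1 were to be reported whatever their p. Genes in which a common null allele sets the level were passed over. Members that the text names outside this rule are said to be so.

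The arrays were searched for processing batches, since neither the labels nor the table gives a date. Among 9197 probe sets with a mean above log2 6, 12 arrays shared 1.79% of their values exactly, pair by pair on average, and 6 other arrays shared 1.88%, while pairs across these sets shared 0.00468%. The first set holds all healthy arrays and HCV 1 to 4, the second HCV 5 to 10. They are called the first and the second processing run here. Because the first run holds both groups, each main value was also computed within it and with the run as a block. No pair of arrays shared more than 2.60% of these values, so no array stood out as a repeat of another.

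The method was tested on simulated arrays with the means and spreads of the 6688 genes. Of 50 genes each, planted with log2 changes of 0.5, 1, 2 and 3, the HCV against healthy comparison recovered 62%, 94%, 98% and 100%, with 11 false calls among 6474 unchanged genes. The remaining 14 genes, the tested members of the heat shock list, had been shifted together by 0.5 to test the list method. Simulated genes and arrays vary independently, which real ones need not do. The estimated correlation between genes was 0.58 in the type I interferon list and 0.42 in the NF-kB and inflammatory list. The simulation therefore does not test the list method on correlated genes. The alternatives covered the marked arrays, the low filter, the value per gene, scaling, variance moderation, array weights, a replicate block, a fold limit, cell composition covariates, estimated correlation, the fry set test, and leaving out each array. Figures were drawn with matplotlib 3.10.9.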

Results

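Gene expression was measured in blood mononuclear cells of 10 donors with chronic HCV infection, sampled before therapy, and of 8 healthy donors, with 1 array each. The series asks which transcripts in circulating cells mark chronic HCV infection. The comparison below set the 10 HCV arrays against 6 healthy arrays, leaving out the 2 healthy arrays that the submitters marked as outliers. Donors were separate people, so the spread between arrays includes the spread between people.

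Blood cells of HCV donors had higher levels of antiviral interferon-stimulated genes and lower levels of inflammatory cytokine genes than cells of healthy donors. Of 6688 genes tested with limma, 64 were higher and 50 were lower in HCV at an adjusted p below 0.05, and 31 of the higher and 29 of the lower genes changed at least 2-fold. The type I interferon list supplied 29 of the 64 higher genes, or 45.3%. The median log2 fold change over all tested genes was 0.0058. An unadjusted p below 0.05 was reached by 957 genes. The count depended on the healthy arrays: it was 19 without healthy array 1, 48 without array 2, 59 without array 4, 56 without array 5 and 74 without array 6. With the platelet score as covariate it was 45, and the split moved from 64 higher and 50 lower to 31 higher and 14 lower. With both marked healthy arrays included limma called 0 genes, although 533 had an unadjusted p below 0.05. With marked array 7 alone added it called 0 genes, 806 being below an unadjusted p of 0.05, and with marked array 8 alone 9 genes, all higher in HCV. Of the 34 named genes that passed, 8 (IFIT1, SIGLEC1, OAS1, IL1A, MMP7, HSD11B1, G0S2 and CHI3L1) kept the call whichever of the 16 arrays was left out. The call was lost in 13 of these 16 fits for IFITM2 and RHOC, in 12 for HMOX1, in 11 for IRF7 and CCL22, in 10 for JAK2, in 8 for BHLHE41, in 6 for CFD, in 4 for ISG15, INHBA and GP1BA, and in 1 to 3 for the other 15.

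**Figure D1:**
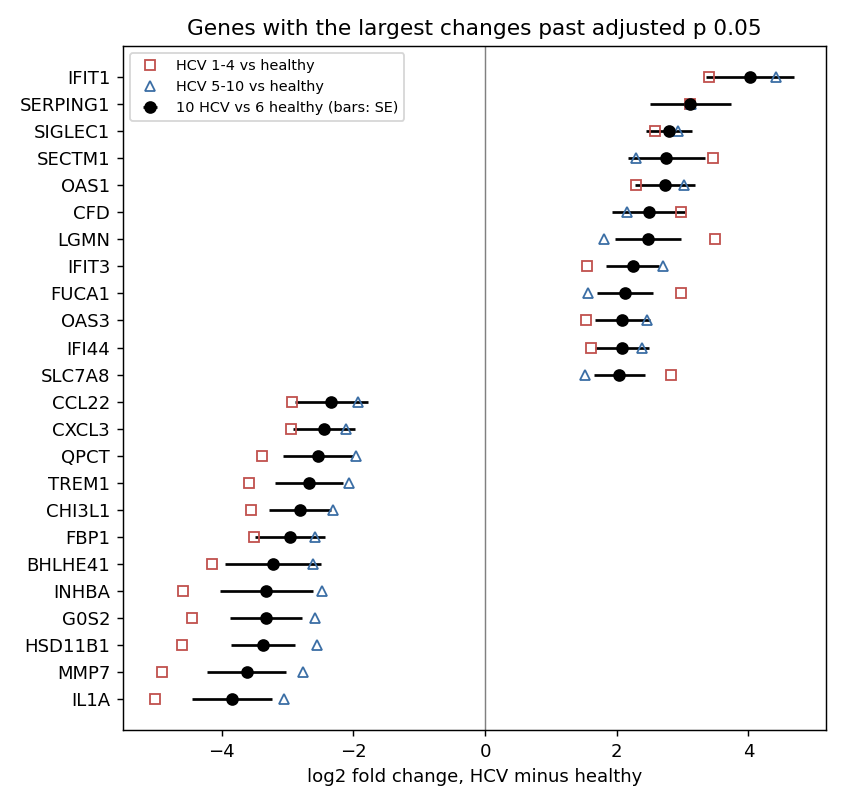
Log2 fold change (HCV minus healthy, horizontal axis) of the 12 highest and 12 lowest genes past the limma threshold. Black points with SE bars are 10 HCV against 6 healthy arrays, squares are HCV 1 to 4 and triangles HCV 5 to 10 against the same 6 healthy arrays. IFIT1 lies at 4.02 and IL1A at -3.84, and each gene has the same sign in all 3 comparisons. The genes were chosen on the pooled comparison, which holds the arrays of the other comparisons, so equal signs are no independent support.

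The largest increase was that of IFIT1, an interferon-induced protein that binds viral RNA. Its mean log2 level was 3.70 ± 0.93 (SD, n = 6) in healthy and 7.72 ± 1.59 (SD, n = 10) in HCV arrays (log2 fold change 4.02, SE 0.67, limma adjusted p = 0.0097), and 9 of 10 HCV arrays lay above all 6 healthy arrays. Of the 12 genes with the highest fold changes, 7 were members of the type I interferon list. Besides IFIT1 these were SERPING1, a complement inhibitor, SIGLEC1, a sialic acid receptor of monocytes and macrophages, OAS1 and OAS3, which make the activator of the antiviral nuclease RNase L, and IFIT3 and IFI44. SIGLEC1 rose 6.93-fold (log2 fold change 2.79, SE 0.35, limma adjusted p = 0.0039), and all 10 HCV arrays lay above all 6 healthy arrays. OAS1 rose 6.65-fold and OAS3 4.25-fold, likewise without overlap. SERPING1 had a log2 fold change of 3.12, from a healthy mean of log2 2.27 that sits near the floor of the scale. The healthy mean of IFIT1 was below the filter level of log2 4 too, so the sizes of both changes depend on the background correction and no fold is given. In the first run alone neither passed, IFIT1 at a log2 fold change of 3.41 (limma adjusted p = 0.0962) and SERPING1 at 3.11 (adjusted p = 0.0514).

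In the type I interferon list as a whole, 29 of 53 tested members rose, 0 fell and 24 did not pass; adjusted over the list alone, 50 rose. The fold change was positive for 52 of the 53, LAMP3 being the exception, named after its value was seen, at a log2 fold change of -1.11. The list's median log2 fold change was 1.04 (camera adjusted p = 2.04e-45), and the adjusted p = 0.191 with an estimated correlation between genes. The list's score was 7.88 ± 0.25 (SD, n = 6) in healthy and 9.11 ± 0.54 (SD, n = 10) in HCV arrays, a difference of 1.22 (SE 0.20, exact permutation p = 0.0005, adjusted p = 0.0155). All 10 HCV arrays lay above the highest of these 6 healthy arrays, HCV 2 at 8.221 only just above healthy array 4 at 8.217. The marked healthy arrays, left out here, scored 9.42 and 8.23, inside the HCV range.

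Among the interferon-response genes to be reported whatever their p, MX1, an antiviral GTPase, rose 3.96-fold (SE 0.38 on the log2 scale, limma adjusted p = 0.017) and ISG15, a ubiquitin-like modifier, rose 3.16-fold (SE 0.35, limma adjusted p = 0.024). IRF7, a transcription factor of interferon genes, rose by 1.04 on the log2 scale and TNFSF10, the death ligand TRAIL, rose 2.54-fold. For IRF7 no fold is given, since 2 healthy arrays held exactly the same value. Within the first run alone none of these passed, with log2 fold changes of 1.45 for MX1 (limma adjusted p = 0.118), 1.03 for ISG15 (0.139), 0.58 for IRF7 (0.140) and 0.99 for TNFSF10 (0.0704). Those that did not pass in limma were IFI44L (log2 fold change 2.62, SE 0.67, adjusted p = 0.057), USP18 (1.88, SE 0.51, adjusted p = 0.071), CXCL10 (2.74, SE 0.79, adjusted p = 0.096) and IFI27 (1.75, SE 0.57, adjusted p = 0.14). The IFI27 difference could not be separated from the processing run: its log2 value was 1.73 ± 0.00023 (SD, n = 6) in healthy arrays and averaged 1.76 in HCV 1 to 4 and 4.63 in HCV 5 to 10. USP18, with a healthy mean of 3.02, below the filter level, also moved with the run: its log2 fold change was 0.68 within the first run (limma adjusted p = 0.409) and 2.69 for HCV 5 to 10 (adjusted p = 0.000368). Some arrays of HCV 5 to 10 held exactly the same USP18 value, 5.81.

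**Figure D2:**
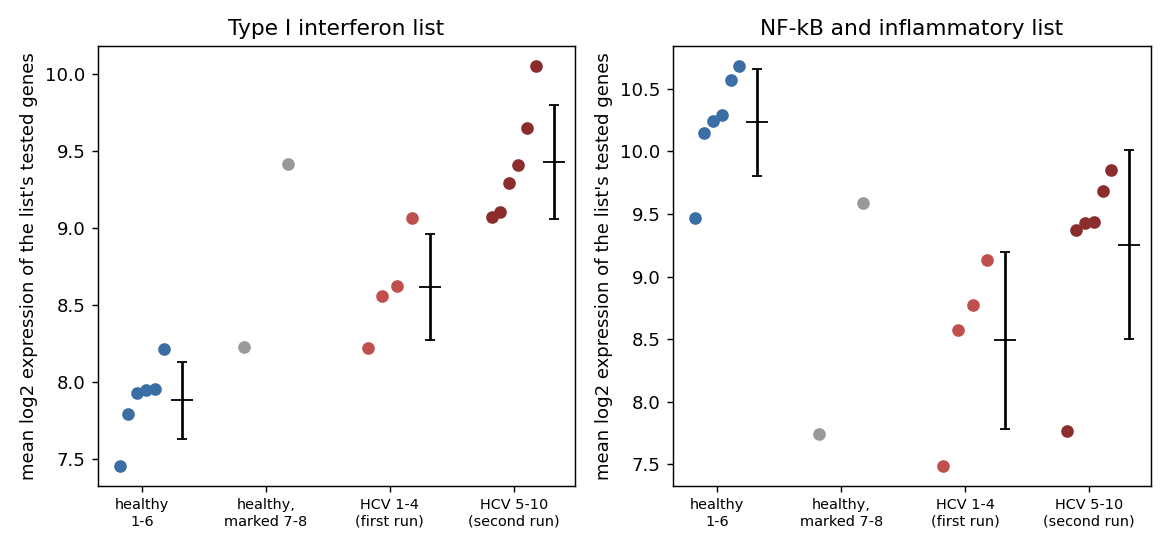
Score of each array (vertical axis: mean log2 expression of the tested genes of the list) for the type I interferon list and the NF-kB and inflammatory list. Points are arrays sorted by value, and bars are mean ± SD of healthy arrays 1 to 6, HCV 1 to 4 and HCV 5 to 10; the marked arrays have no bar. All 10 HCV arrays lie above healthy arrays 1 to 6 in the first list and 8 of 10 lie below them in the second.

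The largest decrease was that of IL1A, an alarm cytokine of the interleukin family. Its mean log2 level was 8.67 ± 1.30 (SD, n = 6) in healthy and 4.83 ± 1.23 (SD, n = 10) in HCV arrays (log2 fold change -3.84, SE 0.60, limma adjusted p = 0.0097). The other tested probe set of IL1A also fell but did not pass. MMP7, a secreted matrix protease, had a log2 fold change of -3.62, and HSD11B1, the enzyme that regenerates active cortisol, of -3.37 (SE 0.48, limma adjusted p = 0.0061); all 10 HCV arrays lay below all 6 healthy arrays for both. INHBA, the subunit of activin A, had -3.32 and the chitinase-like glycoprotein CHI3L1 -2.81. In these 5 genes 2 or more HCV arrays of a run held exactly the same value, and these values differed between the runs. The repeated value of CHI3L1 was 5.85 in HCV 1 to 4 and 7.90 in HCV 5 to 10, that of MMP7 3.44 and 5.50, that of IL1A 3.76 and 4.94, and that of INHBA 2.19 and 4.79, while HSD11B1 had one only in HCV 5 to 10, at 4.68. Their changes are therefore given on the log2 scale and not as folds, since the size mixes repeated values that are specific to a run. Within the first run the log2 fold changes were -5.02 for IL1A (limma adjusted p = 0.00898), -4.91 for MMP7 (0.0041), -4.61 for HSD11B1 (0.00125), -3.56 for CHI3L1 (0.0401) and -4.59 for INHBA, which did not pass (0.0514). G0S2, an inhibitor of triglyceride breakdown, was 10.01-fold lower, BHLHE41, a repressor of the circadian clock, 9.36-fold, and FBP1, an enzyme of gluconeogenesis, 7.76-fold. TREM1, a receptor that amplifies inflammatory responses of myeloid cells, was 6.39-fold lower, QPCT, glutaminyl cyclase, 5.79-fold, and the chemokines CXCL3 and CCL22 were 5.45-fold and 5.04-fold lower. For all genes from G0S2 to CCL22 the decrease was larger within the first run than for HCV 5 to 10. The log2 fold changes were -4.45 and -2.58 for G0S2 and -4.14 and -2.61 for BHLHE41. BHLHE41, FBP1 and CCL22 did not pass within the first run (limma adjusted p = 0.0643 for each).

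Of the 24 tested members of the NF-kB and inflammatory cytokine list, 4 fell, 0 rose and 20 did not pass; adjusted over the list alone, 13 fell. IL1A and CXCL3 fell, as did CXCL8 and TRAF1, named after their values were seen. In 23 of 24 members the fold change was negative. The median log2 fold change was -0.98 (camera adjusted p = 1.53e-13), and the adjusted p = 0.305 with an estimated correlation. The score was 10.23 ± 0.43 (SD, n = 6) in healthy and 8.95 ± 0.80 (SD, n = 10) in HCV arrays, a difference of -1.28 (SE 0.31, exact permutation p = 0.0026, adjusted p = 0.0406), and 8 of 10 HCV arrays lay below all 6 healthy arrays. With marked array 8 added to the healthy group the difference was -0.93 (exact permutation p = 0.0539). The CD14 monocyte score differed by -0.07 (SE 0.25, exact permutation p = 0.793), and the platelet score by -0.62 (SE 0.37, exact permutation p = 0.166).

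Of the 12 genes with the highest fold changes, 5 lay outside the type I interferon list. SECTM1, an interferon-inducible myeloid protein, rose 6.75-fold (SE 0.58 on the log2 scale, limma adjusted p = 0.025). CFD, complement factor D, rose 5.60-fold. LGMN, a lysosomal cysteine protease, rose 5.57-fold and FUCA1, a lysosomal fucosidase, 4.36-fold, the latter from a mean log2 level of 11.2 ± 0.79 (SD, n = 6) to 13.3 ± 0.92 (SD, n = 10). The amino acid transporter SLC7A8 rose 4.11-fold, with all 10 HCV arrays above all 6 healthy arrays. JAK2, a kinase of cytokine receptors, rose 1.86-fold and CASP10, a caspase of death receptor signalling, 1.76-fold. For CASP10 some arrays of HCV 5 to 10 held exactly the same value, 5.89, so the size of its rise is uncertain. The other tested probe set of JAK2 also rose but did not pass. HMOX1, heme oxygenase, rose by 1.12 on the log2 scale, 2 healthy arrays holding exactly the same value. IFITM2, an interferon-induced membrane protein, rose 1.62-fold, while RHOC, a small GTPase, fell by 0.53 on the log2 scale and GP1BA, a platelet adhesion receptor, fell by 1.11. In the first run alone HMOX1 (limma adjusted p = 0.0179) and GP1BA (0.0401) passed, while JAK2 (0.155), CASP10 (0.0862), IFITM2 (0.245) and RHOC (0.127) did not. With the run as a block JAK2 (0.172), IFITM2 (0.220) and RHOC (0.0562) did not pass, while CASP10, HMOX1 and GP1BA did.

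The interferon gamma response list was shifted upward, with 3 of 23 members risen, among them SECTM1 and JAK2, 20 not passing, 8 risen when adjusted over the list alone and a median log2 fold change of 0.43 (camera adjusted p = 1.24e-05, adjusted p = 0.522 with an estimated correlation). In the MHC class II list, 1 of 14 members rose, the lysosomal protease LGMN, with a median of 0.40 (camera adjusted p = 0.000583, adjusted p = 0.522 with an estimated correlation). In the MHC class I list 0 of 18 members passed, with a median of 0.11 (camera adjusted p = 0.0131, adjusted p = 0.794 with an estimated correlation), HLA-E having a log2 fold change of 0.28 (SE 0.085, limma adjusted p = 0.114). Without healthy array 3 this list had a median of 0.089 and a camera adjusted p of 0.0856, and without HCV 7 these were 0.108 and 0.0739. Among B cell markers 0 of 11 passed, with a median of 0.42 (camera adjusted p = 0.0321, adjusted p = 0.794 with an estimated correlation); BLNK, an adaptor of the B cell receptor, had 1.09 (SE 0.37, limma adjusted p = 0.16). The B cell call was lost with the platelet score as covariate (median 0.048, camera adjusted p = 0.869), with the monocyte score as covariate (0.38, 0.0583), without the low filter (0.26, 0.0551) and with a filter at log2 6 (0.45, 0.0734). It was also lost without healthy array 1 (median 0.35, camera adjusted p = 0.0846), 2 (0.43, 0.0682), 5 (0.34, 0.0700) or 6 (0.33, 0.0810) and without HCV 3 (0.24, 0.109), 5 (0.39, 0.0778), 7 (0.38, 0.0981) or 10 (0.42, 0.0680). Without healthy array 3 the median was 0.64 and the list passed. The scores of these upward lists did not pass the exact permutation test. Its adjusted p was 0.239 for interferon gamma, 0.195 for MHC class II, 0.479 for MHC class I and 0.525 for B cell markers.

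The lists of oxidative phosphorylation, ribosomal proteins and cholesterol synthesis were shifted downward by small amounts in camera with the preset correlation. Their scores did not pass the exact permutation test (adjusted p = 0.195, 0.328 and 0.195). In the oxidative phosphorylation list 0 of 27 members passed and 25 had lower values in HCV, with a median log2 fold change of -0.11 (camera adjusted p = 0.000186, adjusted p = 0.522 with an estimated correlation). All 20 ribosomal protein genes tested were lower, none of them past the threshold, with a median of -0.08 (camera adjusted p = 0.00523, adjusted p = 0.794 with an estimated correlation). In the list of cholesterol synthesis and uptake 0 of 11 members passed, 1 fell when adjusted over the list alone, and the median was -0.14 (camera adjusted p = 0.0177, adjusted p = 0.522 with an estimated correlation). The call was lost without healthy array 1 (median -0.090, camera adjusted p = 0.0708) or HCV 2 (-0.096, 0.0557), with both marked arrays (-0.060, 0.175) or array 7 (-0.069, 0.0768) included, and for HCV 5 to 10 alone (-0.10, 0.0727). SQLE, squalene epoxidase, had a log2 fold change of -0.84 (SE 0.25, limma adjusted p = 0.106). No list passed camera with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, called 2 lists, type I interferon (adjusted p = 0.0055) and NF-kB and inflammatory cytokines (adjusted p = 0.039).

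**Figure D3:**
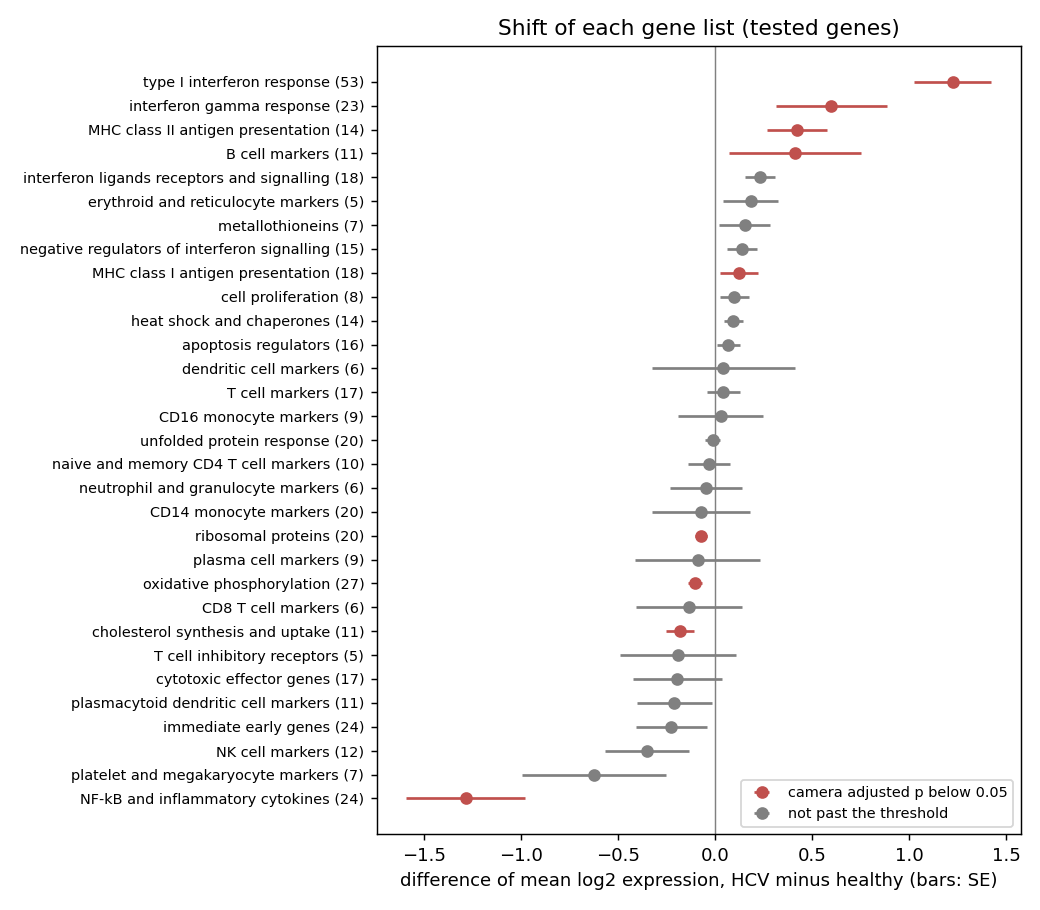
Difference of the mean log2 expression of each list (horizontal axis, HCV minus healthy, 10 against 6 arrays) with SE bars, for the 31 lists with at least 5 tested genes (number in brackets). Red marks the 9 lists past the camera threshold with a preset correlation, from 1.22 for type I interferon to -1.28 for NF-kB and inflammatory cytokines. Of these, only the type I interferon and the NF-kB and inflammatory list also passed the adjusted exact permutation test of the score.

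Markers of most blood cell types did not pass camera. The adjusted p was 0.935 for T cell, naive and memory CD4 T cell, plasma cell, dendritic cell and plasmacytoid dendritic cell markers, 0.608 for CD8 T cell markers and 0.0692 for NK cell markers. It was 0.975 for CD14 monocyte and for neutrophil and granulocyte markers, 0.542 for CD16 monocyte, 0.119 for platelet and megakaryocyte and 0.481 for erythroid and reticulocyte markers. In the NK list IL2RB, a subunit of the interleukin receptor, had a log2 fold change of -0.35 (SE 0.10, limma adjusted p = 0.102). Among CD14 monocyte markers, 3 rose and 2 fell when adjusted over the list alone; TLR4, the receptor of bacterial lipopolysaccharide, had 1.27 (SE 0.35, limma adjusted p = 0.080). Of the functional lists, the adjusted p was 0.0774 for interferon ligands, receptors and signalling, 0.134 for cytotoxic effector genes, 0.119 for metallothioneins and 0.334 for immediate early genes. It was 0.414 for cell proliferation, 0.608 for T cell inhibitory receptors, 0.909 for apoptosis regulators, 0.935 for heat shock and chaperones, and 0.975 for the unfolded protein response and for negative regulators of interferon signalling. In the list of interferon ligands and receptors TLR7, a sensor of viral RNA, had a log2 fold change of 1.66 (SE 0.43, limma adjusted p = 0.061) and all 10 HCV arrays lay above the 6 healthy arrays compared. The marked healthy arrays had TLR7 at 5.87 and 6.80, above the HCV mean of 5.32. Median, mean and test differed in sign for heat shock, T cell, CD16 monocyte, dendritic cell and neutrophil lists. The lists of HCV entry factors and of hepatocyte transcripts had only 3 and 1 tested genes and were not tested; TFRC had -0.56 (SE 0.23, limma adjusted p = 0.252) and SERPINA1 -0.95 (SE 0.27, limma adjusted p = 0.085).

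Within the first processing run, which holds HCV 1 to 4 and the healthy arrays, the type I interferon score was higher in HCV by 0.74 and the inflammatory score was lower, at -1.74, the marked arrays being left out. Both reached an exact permutation p of 0.00476, the smallest that 210 splits can give, and the same values hold with the run as a block, since the second run holds HCV arrays only. Limma called 59 genes in the first run, 27 higher and 32 lower, of which 33 were among the 114 genes, and 121 genes with the run as a block, 49 higher and 72 lower, sharing 62. Of the 24 genes at the extremes, 12 passed in the first run alone, 4 of the higher (SIGLEC1, LGMN, FUCA1 and SLC7A8) and 8 of the lower. In the type I interferon list 1 member passed there, although 49 of 53 had positive fold changes. The list's camera adjusted p was 2.04e-13. In the inflammatory list 4 members passed, with a camera adjusted p of 1.03e-15. These camera values, and those with the run as a block, use the preset correlation of 0.01. With an estimated correlation neither list passed in the main comparison. For HCV 5 to 10 against the same healthy arrays, a comparison across runs, limma called 101 genes, 70 higher and 31 lower, sharing 64 with the 114; 43 type I interferon members and 1 inflammatory member passed. With the run as a block the adjusted p was 2.41e-14 and 4.95e-16 for these lists, 0.030 for interferon gamma, 0.00148 for MHC class II, 0.030 for oxidative phosphorylation and 0.0135 for cholesterol, while MHC class I (0.260), B cell markers (0.0536) and ribosomal proteins (0.179) no longer passed. In the first run alone interferon gamma (0.0509) did not pass either. MHC class II (0.00125), oxidative phosphorylation (0.0129) and cholesterol (0.00601) did pass, and MHC class I (0.314), B cell markers (0.103) and ribosomal proteins (0.103) did not. Among HCV arrays the type I interferon score was higher in HCV 5 to 10 than in HCV 1 to 4 by 0.81 (exact permutation p = 0.0095), a difference that the design cannot separate from the run.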

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

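The tests of processing run, monocyte share, handling, labels and raised interferon response below, and the splits within the first run, were chosen after the results were seen; the count over other splits of all 16 arrays was planned.

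Dixon's test was run on the named genes and the list scores within healthy and within HCV arrays. In 184 such groups of values it found 17 single arrays apart from the rest of their group, 13 healthy and 4 HCV, where chance alone gives about 1 in 20. Healthy array 4 had a log2 value of 3.28 for SERPING1, above a median of 1.99 in the others, and 10.1 for TREM1, above 8.81. Healthy array 1 was low for SIGLEC1, at 4.26, for OAS1, at 4.30, and for TLR7, at 2.10. Healthy array 3 was low for IL1A, at 6.13, and for CXCL3, at 7.97, and healthy array 2 was low for TNFSF10, at 9.58. Healthy array 5 had 8.92 for LGMN, above a median of 7.40 in the others, and only 8.09 for the antibody joining chain JCHAIN, against 11.1. Its plasma cell score was low, at 7.92, while its platelet score, 9.81, and its erythroid score, 7.71, were high. HCV array 3 had a low platelet score of 5.91, against a median of 8.41 in the other HCV arrays. HCV array 6 was high for JAK2, at 9.03, HCV array 4 was high for the endoplasmic reticulum stress gene HERPUD1, at 11.97, and HCV array 2 was low for IFITM2, at 10.6.

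Both healthy arrays that the submitters marked as outliers had type I interferon scores above the 6 other healthy arrays, whose scores ran from 7.45 to 8.22. Marked array 7 reached 9.42 and marked array 8 reached 8.23, just above that range.

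The count of 114 changed genes was set against other splits of the same 16 arrays into 10 and 6. Of 100 splits, the real one included, 2 gave as many genes, and 97 of the others gave 0. The highest other count was 126, from a split that put HCV 1, 3, 4, 5, 6 and 9 on one side and all healthy arrays with HCV 2, 7, 8 and 10 on the other. It kept the healthy arrays together and divided each run's HCV arrays, so it did not follow the processing run. The share is under 0.05, but these splits mix the arrays of both runs and leave out the marked arrays, with which the count was 0, so chance is excluded only for free regrouping of these 16 arrays. The count of 59 genes within the first run was set against splits of the 10 of its 12 arrays that are not marked, into 4 and 6. Of 100 such splits out of 210, only the real one, 1 in all, gave as many genes, the highest other count being 4. Chance regrouping of these 10 arrays is excluded, which rests on leaving out 2 healthy arrays that were closer to the HCV mean on most called genes.

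The higher type I interferon score in HCV was weighed against a processing difference and against cell composition. Within the first run, with the marked arrays left out, the score was higher in HCV at an exact permutation p of 0.00476. For these arrays that argues against the run as the whole cause. The separation rests on the exclusion: marked array 7, of the same run, scored 9.42, above the highest of HCV 1 to 4, at 9.07. Marked array 8 scored 8.229, above HCV 2 at 8.221. The CD14 monocyte score differed by at most 0.44 at 2 SE above its estimate, below the interferon difference of 1.22 (SE 0.20). That argues against a larger share of monocytes only as far as this score measures the share. Of its tested members 10 were higher and 10 lower in HCV, so their mean is a mixed measure. A response to infection therefore remains a candidate explanation, as a hypothesis, since other differences between the donor groups were not tested. The part of the difference that lies between HCV 5 to 10 and HCV 1 to 4 cannot be assigned to donors or to the run.

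The lower inflammatory score in HCV was weighed in the same way. Within the first run, with the marked arrays left out, it was lower at an exact permutation p of 0.00476, which for these arrays argues against the run as the whole cause. The separation rests on the exclusion. Marked array 8, of the same run, scored 7.74, below HCV 1 (8.77), HCV 2 (9.13) and HCV 4 (8.57), whereas marked array 7, at 9.59, lay above HCV 1 to 4. The monocyte score difference was -0.57 at 2 SE below its estimate, smaller than the inflammatory difference of -1.28 (SE 0.31). That argues against a smaller share of monocytes only as far as this score, whose members moved both ways, measures the share. Activation of the healthy cells during handling could not be told apart from a difference in the donors: the immediate early list differed by -0.22 (SE 0.18), and such transcripts return to baseline before cytokine transcripts do. Activated healthy cells and dampened HCV cells may thus both give this pattern. A smaller share of platelets in HCV stays open as a part of it. The platelet score differed by -0.62 (SE 0.37), which at 2 SE below its estimate reaches beyond the inflammatory difference. With the platelet score as covariate the inflammatory difference was smaller in size but stayed negative (exact permutation p = 0.00762). With that covariate limma called 14 lower genes, against 50 in the main comparison.

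The place of the marked arrays was weighed as a wrong label against a raised interferon response in a healthy donor. On array 7, 50 of 53 type I interferon and 13 of 24 inflammatory members were closer to the HCV mean, but its inflammatory score of 9.59 lay inside the range of both groups, so a wrong label stays open. Its interferon score exceeded the other healthy arrays by more than their SD, but 73 of the 85 called genes outside that list were closer to the HCV mean too. A raised interferon response alone may not account for that, and it stays open at least as a part of the pattern. On array 8, both scores lay inside the HCV range and outside the healthy range, which met the criterion for a wrong label as first set; the further criterion, most members of each list closer to the HCV mean, was added after that was seen. Only 13 of 53 interferon members met it, against 23 of 24 inflammatory members, and its interferon score lay just above the healthy maximum of 8.22. By contrast, 82 of the 85 called genes outside the interferon list and all 50 genes lower in HCV were closer to the HCV mean. A raised interferon response alone may account for this even less than on array 7, and a wrong label stays open. The called genes were chosen in a fit without the marked arrays, so a left-out healthy array may lie closer to the HCV mean for that reason. No such count was made for an unmarked healthy array left out of the fit, so these counts have no baseline.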

How the results depend on the processing

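Alternatives on the processing run and on single marked arrays, and all those of the inflammatory score, were chosen after seeing the data. The type I interferon score kept its direction and an unadjusted exact p below 0.05 under all 30 alternatives on the log2 scale (0.74 to 1.55, largest exact p 0.0313). Leaving out 1 array gave 1.11 to 1.32. The inflammatory score did so under 29 of 30 (-1.74 to -0.93, and -1.44 to -1.12 without 1 array). The exception was marked array 8 included (-0.927, exact p 0.0539). These p-values are not adjusted over the 31 lists. None of these alternatives set the first run alone with the marked arrays in the healthy group. The count of 114 genes stayed within 1.5 times under 20 of 34 alternatives. It was 0 with both marked arrays included and with array 7 alone, 9 with array 8 alone, 30 without the low filter, which tests more genes, 60 with a fold limit of 2, which can only remove genes, 212 with array weights, 172 with the monocyte score (97 higher, 75 lower) and 45 with the platelet score as covariate (31 higher, 14 lower), and 59 for HCV 1 to 4, which uses fewer arrays. Leaving out 1 array gave 19 (healthy 1) to 134 (HCV 7) genes. The count of 9 lists was 0 with an estimated correlation, 2 with fry and 5 for HCV 1 to 4, and 7 to 12 without 1 array. Beyond the constructions named, the cause was not tested. Replicate numbers do not pair the donors: correlations of same-numbered arrays ran from -0.23 to 0.20 over 6 pairs, and the replicate block called 86 genes, 40 of them among the 114. With that block the scores were 0.984 and -1.70, and 6 of the 9 lists passed. Of 1998 values of named genes under alternatives, 1652 kept direction and side of the threshold, 320 lost the call, 25 gained one and 1 reversed, CCL5 with the marked arrays included (0.099, against -0.20). All 34 named genes that were called lost the call with both marked arrays included. The 22 lists that did not pass have no direction to keep: in 701 values under alternatives the camera direction differed 86 times and the threshold was passed 25 times, NK cell markers among them. Signal near the floor limits the sizes of changes in 7 of the 61 named genes, 4 of them among the 24 at the extremes, whose lower mean was below log2 4.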

Other observations

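The test of aligned gene means below was chosen after the values were seen.

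Both marked healthy arrays had low levels of lymphocyte effector transcripts. The CD8 T cell score was 8.73 on marked array 7 and 9.60 on marked array 8, against 10.34 to 11.46 on the 6 other healthy arrays and 9.63 to 11.9 on the HCV arrays. The NK cell score was 7.83 and 8.10, against 8.54 to 9.87 and 8.13 to 9.22, and the cytotoxic effector score was 9.08 and 9.35, against 10.00 to 11.2 and 9.39 to 10.8. On these 3 lists, which share members, both marked arrays lay below every healthy and every HCV array. The CD14 monocyte scores, 11.7 and 11.1, lay inside the healthy range of 10.44 to 11.8. Of the 50 genes lower in HCV, array 7 was closer to the HCV mean for 44 and array 8 for 50; of the 64 higher genes these numbers were 57 and 41.

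Many tested genes hardly varied within a set of arrays, in either run. Of the 6688, 567 had an SD below 0.1 over HCV 5 to 10, 6 of them among the 114 called genes, and 1387 had one over the 6 healthy arrays, all from the first run. Both held for 264 genes. CHI3L1 had a mean of 7.95 and an SD of 0.087 over HCV 5 to 10. In addition, 4 probe sets, IFI27 among them, were constant within both runs and more than 1 log2 unit apart between them.

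A hypothesis is that the submitters aligned gene means between the processing runs. Over 9197 probe sets with a mean above log2 6, the median absolute difference of gene means between the runs was 0.0516, smaller than in all of 100 random splits of the 18 arrays into 6 and 12 (lowest 0.0656, median 0.0809). This may point to an adjustment per gene. A shift of the second run alone would alter fold changes that rest on HCV 5 to 10 and leave those within the first run as they are. Other forms of adjustment could alter both. The 114 called genes and the pooled fold changes, SEs and p-values rest partly on HCV 5 to 10. The inflammatory score was 10.23 in healthy arrays, 8.49 in HCV 1 to 4 and, in between, 9.26 in HCV 5 to 10. Aligned means could give such a place between the groups. The type I interferon score was 7.88, 8.62 and 9.43, highest in HCV 5 to 10, which aligned means alone would not give. Which step produced the small difference between the runs was not tested.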
